A study of Mus musculus with 3 samples.

How the data were processed

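Binding was profiled in 3 libraries from mouse C17.2 neural progenitor lines, with 1 library per group. Line C17.2a stably expressed a tagged thyroid hormone receptor alpha (TRα), and line C17.2b a tagged thyroid hormone receptor beta (TRβ). Both receptors carried a protein G tag and were pulled down with IgG beads (chromatin affinity purification, ChAP-seq), whereas retinoid X receptor (RXR) was precipitated from C17.2a with a pan-RXR antibody and protein A beads (ChIP-seq), per the labels. All cells were untreated and had been kept in serum-free medium before fixation.

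Upstream steps are known only in part. Per the submitters' processing notes, CASAVA 1.7 and Bowtie 0.12.7 were used with the mouse build mm9. Per the file headers, peaks were called with MACS on each library alone, without a control file, at a p-value limit of 0.0001, with a tag size of 36 bp, a model fold of 5 and an effective genome size of 2.7 Gb. The MACS version is not given in the sources used here. The band width was 500 bp for TRα and TRβ and 300 bp for RXR, and the modelled shift distance d was 139, 56 and 174 bp for TRα, TRβ and RXR, per the file headers. MACS extends tags by d, so d and the band width bear on the width of the peaks that were deposited.

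Each deposited list gives the position, summit and 3 measures of every peak. The count of tags inside a peak is a whole number that the authors did not normalize. The score is minus 10 times log10 of the p-value from MACS, as deposited by the authors. The fold enrichment is a ratio deposited by the authors. It was read here as tags over a regional background of the same library, since the headers name regional windows and no control file but do not define the fold. Score and fold are the authors' own values for a peak and were used only to rank, filter or describe peaks within a list. With no control library, regions that collect tags in any pull-down were not removed by the calling.

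Starts of RXR peaks were raised by 1 bp, since lengths in that list showed a start counted from 0, and 1 TRβ start below 1 on the mitochondrial sequence was set to 1. Peaks of 2 lists were called overlapping when they shared at least 1 bp. Overlap shares were set against 1000 circular shifts of a list along each chromosome, and 95% intervals came from 10000 resamplings of chromosomes, or 500 for correlations. Shares per score decile carry 95% Wilson intervals. TR regions were built by merging overlapping TRα and TRβ peaks and were called shared, TRα-only or TRβ-only. Depth-scaled tags were the tags of a peak per 1000000 unique tags of its library. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9.

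The overlap step was tested on simulated data with lists of 7174 and 10021 peaks, the sizes of the TRα and TRβ lists. Simulated overlaps of 0, 10 and 50% were returned as 0.362, 10.3 and 50.2%. The interval for a difference of shares held the simulated difference in 93.5% of 200 simulated sets. Simulated peaks were independent of each other, so the clustering of peaks in the deposited lists was not covered by these tests.

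Unique tags numbered 19786966 for TRα, 16556350 for TRβ and 16033622 for RXR, per the file headers. With 1 library per group there was no replicate check and no p-value between receptors, and the intervals cover counting error or variation between chromosomes only. Receptor, cell line and library differed together between TRα and TRβ.

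The overlap shares, the RXR shares by region class and the rank differences, with their tests and a set of alternatives, were fixed before the data were examined. Score deciles, lists of the best 500 peaks, summit distances, tag correlations, shares split by RXR, differences between overlap shares, strong peaks without a partner and runs were added later, as were most tests of explanations in the closing section. These alternatives were a reciprocal overlap of at least 50%, centres within 1 kb, the better-scoring 50% of each list, lists of equal length, autosomes only, and local shifts of 20 to 200 kb as the reference. Windows of 500 bp around summits, removal of 1 Mb bins with 15 or more peaks in any list, and removal of runs of TRβ peaks with the mitochondrial peaks were added after seeing the data. The limit of 15 peaks was set after bin counts had been seen. Peaks named in the text are the 10 with the highest score in each list, the 10 regions of all 3 lists with the lowest sum of ranks, and the 1 Mb bin with the most peaks, with others named as chosen after their values were seen. The position of 1 run of TRβ peaks is not reported here.

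Planned comparisons with transcription start sites, with fixed gene lists and with the direct-repeat motif of thyroid hormone response elements were not run, because no genome or annotation of the build of the peak lists was used here. For the same reason no gene is named and the position of peaks relative to exons and introns was not analysed here.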

Results

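Genome-wide binding of the thyroid hormone receptors TRα and TRβ was mapped in mouse C17.2 neural progenitor cells, with 1 line expressing each tagged receptor. TRα and TRβ are nuclear receptors that bind DNA mostly as heterodimers with RXR, also in the absence of hormone. RXR was mapped in the TRα line. The TRα, TRβ and RXR libraries held 20259748, 19842907 and 16654006 tags, of which 97.7%, 83.4% and 96.3% were unique. There was 1 library per group, so differences between lists had no replicate check. All positions are given on mm9.

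The lists held 7174 TRα peaks, 10021 TRβ peaks and 7194 RXR peaks. TRβ peaks were the narrowest, with a median width of 168 bp against 559 bp for TRα and 701.5 bp for RXR. A median TRβ peak held 8 tags, a median TRα peak 21 and a median RXR peak 22. TRβ peaks had been called with a modelled shift distance of 56 bp, the shortest of the 3 lists, and 16.6% of the TRβ tags were repeats. Whether that fragment model held was not tested, and it bears on the TRβ widths, scores and overlap shares. The peaks covered 4.31 Mb and 1.12% of the unique tags for TRα, 1.94 Mb and 0.832% for TRβ, and 5.35 Mb and 1.32% for RXR. Scores under 50, near the lower limit of 40, were found for 42.4% of TRα, 67.0% of TRβ and 45.1% of RXR peaks. In all 3 lists the 1 Mb bin with the most peaks was chromosome Y from 1 to 2 Mb, with 39 TRα, 76 TRβ and 31 RXR peaks.

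The comparison of TRα with TRβ asked how far the receptors occupied the same sites. Of the 7174 TRα peaks, 1731 (24.1%, 95% interval 21.4 to 28.2) overlapped a TRβ peak. From the TRβ side, 1886 of 10021 peaks (18.8%, 16.4 to 22.3) overlapped a TRα peak. Where the lists met, summits lay a median of 29 bp apart, and 88.1% of 1731 pairs lay within 100 bp. Shifted TRα peaks met a TRβ peak in 0.350% of cases on average, so that the observed share was 69.0-fold higher, and 44.2-fold higher than with local shifts. For TRβ peaks the corresponding ratios were 67.8 and 43.8. None of the 1000 shifts reached the observed share in either direction. Requiring a reciprocal overlap of 50% lowered the shares to 4.99% and 3.57%, a rule that peaks of unequal width rarely meet. In the better-scoring 50% of each list the TRβ share with a TRα peak was 28.3%, and with lists of equal length TRβ peaks met TRα peaks in 24.7% and TRα peaks met TRβ peaks in 22.7% of cases, the opposite order.

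Overlap followed the strength of the peak. In the TRα list, 74.0% of peaks in the top score decile (Wilson interval 70.6 to 77.0) and 5.16% in the bottom decile (3.77 to 7.03) met a TRβ peak. In the TRβ list the shares with a TRα peak were 76.8% (74.1 to 79.3) and 3.89% (2.86 to 5.28). TRα peaks that met TRβ had a median rank percentile of 80.7, against 40.6 for the other TRα peaks, a difference of 40.1 points (38.4 to 41.8). TRβ peaks that met TRα had a median rank percentile of 87.3 against 42.4, a difference of 44.9 points (42.8 to 46.6).

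**Figure D1:**
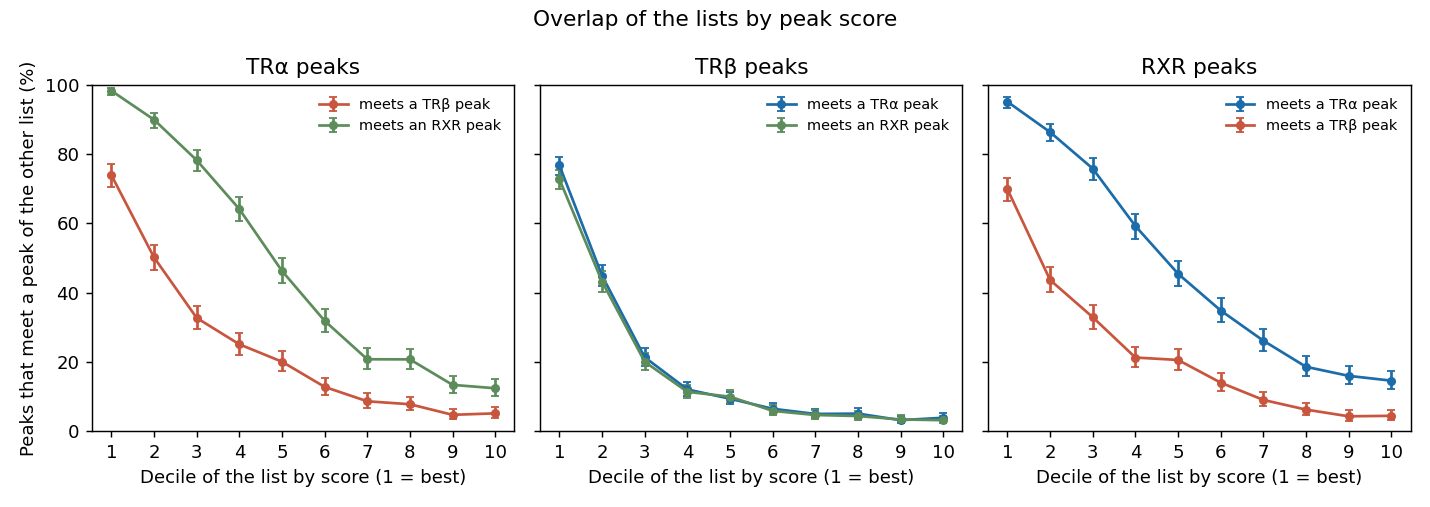
Share of peaks (%) that overlapped a peak of another list, by decile of the authors' score within the TRα, TRβ and RXR lists (1 is best), with Wilson 95% intervals as bars. In the top decile 98.3% of TRα peaks met RXR and 74.0% met TRβ, whereas both curves of the TRβ list start at 76.8% and 72.8% and lie close together.

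TRα and RXR, both mapped in C17.2a, shared the most sites. RXR was precipitated from cells that held the protein G-tagged TRα, and direct recovery of tagged TRα by the antibody was not tested. An RXR peak overlapped 3417 TRα peaks, or 47.6% (45.4 to 50.02), and a TRα peak overlapped 47.2% of RXR peaks. This was 114-fold above shifted peaks and 64.4-fold above locally shifted peaks. In the top score decile 98.3% of TRα peaks met RXR (Wilson interval 97.1 to 99.04), and 95.1% of RXR peaks met TRα (93.3 to 96.5). The RXR share of TRα peaks exceeded their TRβ share by 23.5 percentage points (20.2 to 26.2). With a reciprocal overlap of 50%, a rule that narrow TRβ peaks rarely meet, the difference was 38.8 points (36.4 to 41.2). Summits of TRα and RXR lay a median of 24 bp apart. Depth-scaled tags at the 3396 closest TRα and RXR pairs had a Spearman correlation of 0.774 (0.752 to 0.796), against 0.577 (0.511 to 0.646) for 1731 TRα and TRβ pairs. These correlations run across pairs of peaks, which are not independent replicates. They cover different pairs, with tags counted over peaks of different width. TRβ peaks that met TRα held a median of 15 tags, against 35 for TRα peaks that met TRβ, so the correlations are not directly comparable.

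TRβ peaks of C17.2b met the RXR peaks of C17.2a less often. Of 10021 TRβ peaks, 1794 (17.9%, 16.0 to 20.7) overlapped an RXR peak, 59.6-fold above shifted and 39.6-fold above locally shifted peaks. The RXR share was 29.7 points higher for TRα than for TRβ peaks (27.6 to 31.6). This difference was 24.1 points (21.8 to 26.0) with lists of equal length. Among the 1000 best peaks of each list, as 500 bp windows, it was 23.2 points (17.4 to 27.9). In the better-scoring 50% of each list it was 35.5 points (32.6 to 37.8), and with a reciprocal overlap of 50% it was 42.5 points (40.3 to 44.8). In the top TRβ decile 72.8% of peaks met RXR (69.9 to 75.4). Among TRβ peaks, the share with TRα exceeded the share with RXR by only 0.918 points (0.258 to 1.73). With a reciprocal overlap of 50%, a rule that narrow TRβ peaks rarely meet, 1.29% of TRβ peaks met RXR and 3.57% met TRα. RXR was mapped in the TRα line alone, so for TRβ the line differed as well as the receptor.

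Regions with peaks of both receptors held RXR peaks most often. Merging gave 15309 TR regions, with 1731 shared, 5443 TRα-only and 8135 TRβ-only. An RXR peak lay at 81.2% of shared regions (78.5 to 83.6), 36.9% of TRα-only regions (34.4 to 39.5) and 3.33% of TRβ-only regions (2.71 to 4.23). The RXR share of shared regions exceeded that of the 13578 single-receptor regions by 64.4 points (61.3 to 67.2). TRα-only regions exceeded TRβ-only regions by 33.6 points (31.0 to 36.2). Neither difference was matched for peak strength. Of the single-receptor regions 8135 were TRβ-only, and TRα peaks that met TRβ had a median rank percentile of 80.7 against 40.6 for the others. The RXR share of TRα peaks itself fell from 98.3% in the top score decile to 12.4% in the bottom decile.

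**Figure D2:**
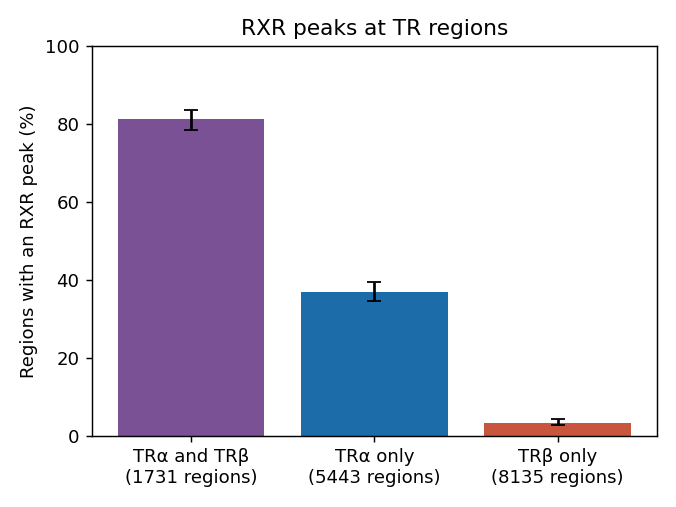
Share of TR regions (%) with an overlapping RXR peak for shared, TRα-only and TRβ-only regions. Bars give the share and error bars the 95% interval from resampling chromosomes. The share falls from 81.2% at shared regions to 36.9% at TRα-only and 3.33% at TRβ-only regions.

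RXR also separated the TRα peaks that met TRβ from those that did not. TRα peaks with RXR met TRβ in 41.1% of cases and those without RXR in 8.65%, a difference of 32.5 points (30.1 to 35.1). The difference was present in each successive 20% of the TRα list by score, at 19.2 points (9.41 to 29.7) among the strongest peaks and between 12.1 and 13.6 points in the others, with intervals above 0 throughout. Among the strongest 20%, 1351 peaks had RXR and only 84 did not. Score still varied within that 20%: from its first to its second decile the RXR share fell from 98.3% to 90.0% and the TRβ share from 74.0% to 50.2%. The split therefore does not fully match for strength. TRβ peaks with RXR met TRα in 84.9% of cases, against 4.41% without. With a reciprocal overlap of 50% the TRα difference of 32.5 points was 4.71 points (3.46 to 5.96). Seen from the 7194 RXR peaks, 1394 (19.4%) met both TR lists, 2004 (27.9%) met TRα alone, 235 (3.27%) met TRβ alone and 3561 (49.5%) met neither.

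Among the 500 best peaks of each list, taken as 500 bp windows around summits, 60.8% of TRα windows met an RXR window (55.4 to 65.8) and 34.2% met a TRβ window (26.1 to 44.1). Of the TRβ windows 36.4% met TRα (30.7 to 43.5) and 33.6% met RXR (27.4 to 42.2). Among regions of all 3 lists, the lowest sum of ranks belonged to chromosome 17 from 36621215 to 36622064 and chromosome 9 from 35112638 to 35113453, each ranked between 1 and 3 in every list. The chromosome 17 region held 402 TRα, 363 TRβ and 333 RXR tags, with folds of 16.9, 18.8 and 14.5. The chromosome 9 region held 358, 357 and 393 tags in the same order. Next came 2 neighbouring regions on chromosome 2, from 98502243 to 98503291 and from 98506258 to 98507643. The former held 540 TRα, 535 TRβ and 661 RXR tags and the latter 613, 411 and 803. Their folds were low next to those of the chromosome 17 region, at 5.7, 7.01 and 4.45 for the former and 5.39, 7.77 and 5 for the latter. Others among the 10 were chromosome 15 from 74915587 to 74917617, chromosome 18 from 40467539 to 40468193 and chromosome 4 from 70038701 to 70039714. The remaining 3 were chromosome 6 from 103598870 to 103599670 and chromosome 9 from 2999863 to 3001587 and from 13422264 to 13423544. No control library entered the calling of these peaks, so regions that collect tags in any pull-down are not told apart from shared binding sites. Depth-scaled TRα and TRβ tags were close in the 10 regions, with a median log2 ratio of -0.07 (quartiles -0.22 and 0.24). The choice by sum of ranks favours regions strong in both lists. Tags were counted over peaks of different width in each list, with medians of 859.5 bp for TRα and 355 bp for TRβ in the 10 regions.

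All 10 top-scoring TRα peaks and all 10 top-scoring RXR peaks met both other lists, whereas 6 of the 10 top TRβ peaks did. Ranked 5 in both the TRα and the RXR list was a broad block on chromosome 17, from 39979842 to 39985877 in the TRα list, with 1995 TRα and 2293 RXR tags. Its folds of 3.25 for TRα and 3.29 for RXR were the lowest among the 10 top peaks of each of these lists. Without a control library it is not told apart from a region that collects tags in any pull-down. The 4 TRβ peaks without a partner lay on the mitochondrial sequence and on chromosome 12 at 75033262 to 75033483 (194 tags) and 75046518 to 75047319 (430 tags). Among peaks with a score of at least 200, 0 of 242 TRα peaks lacked a partner in both other lists, which allows a share of up to 1.24% by 3 counts of the total and 1.51% by the exact interval. For RXR this was 1 of 130 peaks, at chromosome 14 from 9438780 to 9439536 with 64 tags, a peak chosen after its values were seen. For TRβ it was 34 of 219 peaks, or 15.5% (exact interval 10.997 to 21.0).

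Most of these TRβ peaks lay in runs, which were chosen after their values were seen. A run was defined as at least 4 peaks with a score of at least 200, no overlap with another list and gaps of at most 20 kb. The TRβ list had 4 runs with 26 peaks, and the TRα and RXR lists held too few such peaks to form a run. Of these, 3 lay on chromosome 11 from 98617397 to 98625922 (7 peaks, 1084 tags), chromosome 12 from 75027462 to 75047319 (9 peaks, 1441 tags) and chromosome 17 from 87204546 to 87230413 (5 peaks, 368 tags). The peaks of these 3 runs were 104 to 802 bp wide, and 0 TRα and 0 RXR peaks lay within their spans. The gap was first set to 10 kb, which gave 3 runs with 20 peaks, and was widened after further peaks had been seen.

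**Figure D3:**
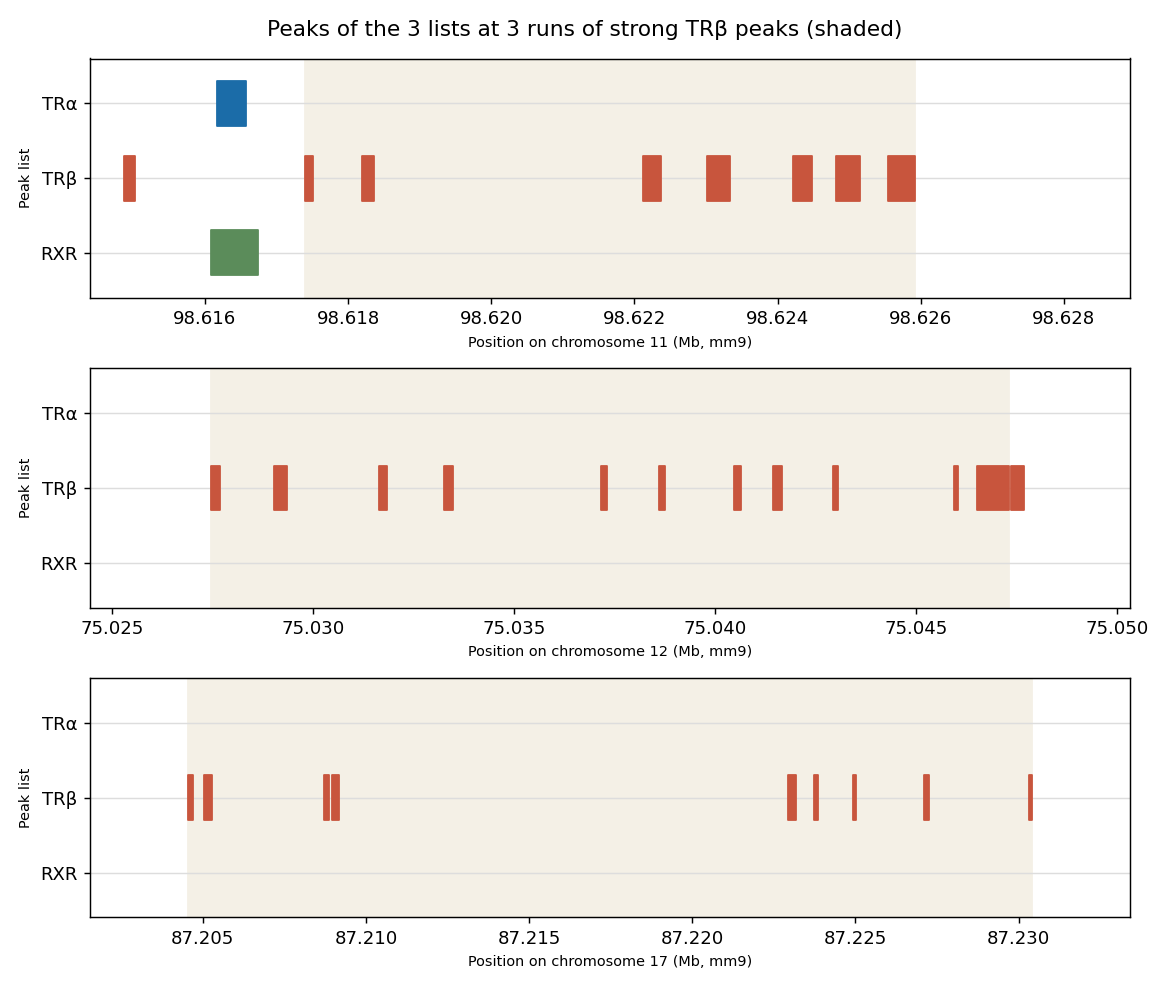
Maps of 3 runs of strong TRβ peaks on chromosomes 11, 12 and 17, with position in Mb (mm9) on the horizontal axis and the peaks of the TRα, TRβ and RXR lists as boxes to scale. The shaded spans hold TRβ peaks and 0 peaks of the other lists. On chromosome 11 a TRα and an RXR peak lie just outside the span.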

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

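A signal outside the nuclear genome was examined only after it had been seen. On the mitochondrial sequence the TRβ list held 3 peaks with 9679 tags, or 0.0585% of the unique tags of that library, whereas the TRα and RXR lists held 0 peaks there. Of these peaks, 10989 to 15708 (4388 tags) and 1 to 5259 (4660 tags) were among the 10 best-scoring TRβ peaks, with folds of 3.18 and 2.18. The lists give no tag counts outside peaks, so the mitochondrial tags of the TRα and RXR libraries are unknown here.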

How the results depend on the processing

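In total, 94 alternative values were computed for 16 results under 9 settings, and 0 reversed direction, 56 stayed within an interval around the first value and 38 left it. That interval was the Wilson interval for shares and their ratios and the chromosome interval for differences. A share has no sign to reverse, so the count of 0 bears only on ratios and differences. The order of the TRα and TRβ shares, which changed with lists of equal length, was not among the 16 results. Of 18 shares that left it, 8 stayed inside the wider chromosome intervals of the report, including all those on autosomes alone, without dense bins and with 500 bp windows. Windows of 500 bp and the removal of dense bins, runs and mitochondrial peaks were chosen after seeing the data. Centres within 1 kb and removal of runs and mitochondrial peaks moved none of the results computed under them. Results below run in the order of the report. With a reciprocal overlap of 50%, TRα peaks with TRβ came to 4.99%, TRβ with TRα to 3.57%, TRα with RXR to 43.8% and TRβ with RXR to 1.29%. The RXR share of shared regions then exceeded that of single-receptor regions by 49.2 points, TRα-only exceeded TRβ-only regions by 42.1 points, and the rank difference in the TRα list was 36.3 points. This rule by construction drops overlaps of narrow TRβ peaks with wider peaks. In the better-scoring 50% of each list the 4 shares were 35.96, 28.3, 62.3 and 26.8%, the RXR differences 56.8 and 46.2 points, and the rank differences 32.5 points for TRα and 41.5 points for TRβ. With lists of equal length, TRα peaks met TRβ in 22.7% (also inside), TRβ met TRα in 24.7% and TRβ met RXR in 23.5% of cases, and shared regions exceeded single-receptor regions by 60.4 points. On autosomes alone, TRα with TRβ was 22.1%, TRβ with TRα 16.99% and TRβ with RXR 16.4%. Without dense bins these were 22.0, 16.7 and 16.3%. With 500 bp windows TRβ with RXR was 17.1%. Local shifts, which keep regional peak density, gave ratios to shifted placement of 44.2 for TRα with TRβ, 43.8 for TRβ with TRα, 64.4 for TRα with RXR and 39.6 for TRβ with RXR. Apart from the reciprocal rule and the local shifts, the cause was not tested. The lowest tag count of a peak was 6 for TRβ and 10 for TRα and RXR, so sites with fewer tags were not called. Depth alone does not explain these limits, since TRα had more unique tags (19786966) than TRβ (16556350). Other settings for start sites, gene lists and the motif were not run, as those comparisons were not. No paired analysis was possible because each group had 1 library.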

Other observations

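Peaks of all 3 lists crowded into a few places. After seeing the bin counts, 20 bins of 1 Mb with at least 15 peaks in any list were set apart, and they held 4.29% of TRα, 6.30% of TRβ and 3.35% of RXR peaks. On chromosome 8 from 19 to 20 Mb there were 75 TRβ, 17 TRα and 14 RXR peaks, and on chromosome X from 121 to 122 Mb there were 61, 23 and 13. Chromosome X carried 4.24% of TRβ, 2.97% of TRα and 2.67% of RXR peaks.

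Some strong sites belonged to TRα and RXR without TRβ, and these were named after their values were seen. The best-scoring were chromosome 3 from 52489447 to 52490214 (100 TRα tags) and chromosome 5 from 104809529 to 104809957 (54 tags), ranked 45 and 57 among TRα peaks. The 2011 TRα peaks with RXR alone had a median score of 67.3, the 1406 with both other lists 107.6, the 325 with TRβ alone 54.5, and the 3432 with neither 45.3. RXR peaks without either receptor (3561) had a median score of 45.5, against 90.0 for the 1394 with both. The best-scoring TRα peak with neither partner, on chromosome 9 from 70111608 to 70111941, held 33 tags and ranked 334.

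The tests of 500 bp windows with equal list lengths and of dense regions were set before their results were seen, and the other tests reported below were chosen after. TRα peaks met RXR peaks of the same line more often than TRβ peaks of the other line. With 500 bp windows and lists of equal length the difference stayed at 24.2 points (20.8 to 26.9). With 500 bp windows alone it was 22.8 points (19.5 to 25.5), which argues against peak width as its cause. The TRβ list was longer than the RXR list, so cutting it could only lower the TRβ share, and the equal lengths are no evidence on list length. Among the 1000 best peaks of each list it was 23.3 points (16.1 to 29.3). TRβ peaks near the score limit can only add to the TRβ share of TRα peaks, so this value is no test of them as its cause. It also cannot show whether a weaker TRβ library lowered the overlap of its best peaks. The cell line shared by TRα and RXR remains a candidate explanation that cannot be told apart from the receptor, since RXR was mapped in C17.2a alone. The RXR precipitation was also made in cells that held TRα with the protein G tag that IgG beads pulled down. Whether the RXR antibody recovered tagged TRα directly was not tested. TRβ peaks of the other line still met RXR 59.6-fold above shifted peaks, but this does not show how much of the difference the shared line made. Whether the TRβ fragment model (d of 56 bp) held was not tested.

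In the runs of strong TRβ peaks that no other list had, a copy number gain stays open. It would raise tags between the peaks and so lower their fold. The median fold of the 26 run peaks differed by only 1.18 (-9.99 to 5.75) from that of TRβ peaks of matched score. The run on chromosome 11 lay lower, at 8.26 against 20.1. The other runs lay higher, as at 20.6 against 17.1 on chromosome 12 and 24.9 against 19.9 on chromosome 17. This test followed 2 others, a count of TRβ peaks in the flanks and the median fold itself, that were judged unable to show a gain. DNA without introns, such as a plasmid carrying a coding sequence, could give such runs, and run peaks were narrower than TRβ peaks of matched score (median difference -100 bp), but the interval of -218.5 to 9.5 bp leaves this open, and exon positions were not used here. Binding by TRβ in C17.2b alone was not tested apart from this and stays open as well.

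TRα and TRβ peaks met far more often than shifted peaks, and the ratio was 69.9 without dense bins and chromosomes X, Y and M. The dense bins held 4.29% of TRα peaks, whereas 24.1% met TRβ. These bins therefore could not have held most of the overlap, and the ratio was no further test of them. Regions that collect tags whatever is pulled down stay possible, since 81.2% of the shared regions also held an RXR peak, a share that both such background and binding with RXR may give without a control library. Such background would give like depth-scaled tags in every library, and the median log2 ratio of TRα to TRβ was 0.94 over all 1731 pairs and 1.04 in the 1206 regions of all 3 lists below the best 200 by sum of ranks. These values go against like tags, but tags were counted over peaks with median widths of 656 bp for TRα and 237 bp for TRβ in the 1206 regions, so they do not decide. The median log2 ratio of TRα to RXR was -0.33 in the 1206 regions, where RXR peaks had a median width of 824 bp. It was -0.41 in the 50 regions with the lowest sum of ranks. For the strongest regions the ratio of TRα to TRβ was 0.43 (0.04 to 0.82) in the 50 with the best RXR rank, and 0.10 (0.01 to 0.28) in the 50 with the lowest sum of ranks, a choice that favours regions strong in both lists and was set aside after both values had been seen.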
